A study of Mus musculus with 6 samples.

How the data were processed

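Gene expression was measured by Affymetrix array in sorted cells from mammary tumours of MMTV-Wnt-1 mice. The 6 arrays held 3 samples labelled tumorigenic and 3 labelled nontumorigenic, and the titles name the same 3 mice, numbered 1 to 3, in both populations. Replicates of a population were therefore separate animals. Per the labels' protocols, total RNA was extracted with a kit for small samples and amplified, and biotin-labelled cRNA was prepared from it by the array maker's procedure. Arrays have no sequencing depth, and their number limits the precision.

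The deposited values are log2 expression values per probe set, which the authors normalised between arrays with RMA (robust multi-array average), per the submitters' processing notes. RMA fits all probes of a probe set jointly and sets the arrays to a common distribution of values, so a change shared by most transcripts would be removed. The version and the background step of RMA are not given in the sources used here. That the scale is log2 was read from the values, whose highest was 13.87 and whose array medians lay between 4.36 and 4.40. At least 2 arrays shared exactly the same value in 16668 probe sets, and 83.2% of these had a mean below a log2 level of 5, so differences between dim transcripts carry less information. The values were used as deposited.

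The table held 45101 probe sets, of which 64 were Affymetrix controls and entered no test. By the platform annotation, 34945 of the others had 1 gene symbol, 932 had several and 9160 had none. Genes were named only from probe sets with 1 symbol. These were matched by Entrez identifier to a table of RefSeq genes of the mouse assembly GRCm38.p6, used only for names: 34741 probe sets were matched with no symbol changed, and 204 kept the platform's symbol. No genome build is named for the array values, and no coordinates are given. The 25% of probe sets with the lowest mean over all 6 arrays, those below log2 2.98, were left out, which kept 33777. Each gene was represented by the named probe set with the highest mean over the 6 arrays, which gave 15027 genes. Named genes whose probe sets differed in sign are named as such.

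The population labelled tumorigenic was compared with the population labelled nontumorigenic by limma (lmFit and eBayes, version 3.58.1 in R 4.3.3), on genes and again on all 33777 probe sets, with all 6 arrays and no covariate. Two-sided p-values were adjusted by the Benjamini-Hochberg method at 0.05. Values are mean ± SD over 3 arrays, and a log2 difference is the labelled tumorigenic mean minus the labelled nontumorigenic mean, with the standard error (SE) from limma. With 3 arrays against 3, an exact permutation test of a single value cannot go below 0.1, so no such test was used. Both populations of a mouse come from 1 animal, so the mouse numbers pair the arrays. The deviations of same-mouse arrays from their population means correlated across genes at 0.079, 0.136 and 0.086 for mice 1, 2 and 3, against values of -0.083 to -0.010 for arrays of different mice. Centring within each population pushes the values of different mice below 0 when those of the same mouse are positive. They are therefore no separate contrast. A fit with the mouse as a block was run as an alternative.

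A total of 33 gene lists were fixed, covering the sort markers, cell types of the mammary tumour and of blood and stroma, signalling pathways, the cell cycle and stress. For each list, members past the threshold were counted over all genes tested and adjusted over the list alone. Lists were tested by camera in limma with the preset correlation of 0.01 between genes, by camera with an estimated correlation, and by fry. The p-values were adjusted over the 32 lists with more than 1 measured member. Camera asks whether the members of a list differ from the other genes. Fry asks whether the members move on balance in a single direction, and its mixed form whether they move in either direction.

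Genes named in the text were the members of the sort marker list, genes past the adjusted threshold, and up to 4 members per list with the smallest p. Where fewer than 12 genes passed in a direction, the 12 genes of that direction with the smallest p and the same sign in all 3 mice were to be given as values. The tests, the lists, this rule and most alternatives were fixed before the data were examined. Alternatives covered the mouse as a block, no dim filter or a filter at 50%, renewed quantile normalisation, centring of each array on its median, a trended and robust prior, array weights, an unmoderated linear model, other ways to represent a gene, and leaving out each array or, for genes and probe sets, each mouse. Lists were not tested again without a mouse, and without an array only by camera at the preset correlation. A pair of alternatives was added after the data were seen: the labelled tumorigenic array of mouse 3 alone against the 3 labelled nontumorigenic arrays, and a leukocyte score as a covariate, which was the mean of the macrophage and myeloid list on each array.

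The procedure was tested on simulated data with the real means and spreads of the 15027 genes and 200 genes changed in each of 5 draws. Adjusted calls recovered 22.1% of changes of 1 log2 unit, 60.6% of changes of 2 and 88.2% of changes of 4, with 23 false calls over the 5 draws. Genes were drawn independently and with the same spread in both populations. Real genes can move together and, as for Ptprc, spread unequally, so these rates need not hold for the real arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.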

Results

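Transcript levels were measured in sorted tumour cells from MMTV-Wnt-1 mice, a transgenic line in which the mouse mammary tumour virus promoter drives Wnt1 in the mammary gland and mammary tumours arise. Tumours of 3 mice were sorted by fluorescence. The population labelled tumorigenic was gated as positive for CD24 and Thy and negative for CD45. The label of the other population, called nontumorigenic, negates the CD24 and Thy gate and also carries CD45-, and it does not settle whether the negation extends to CD45. Each population was hybridised to 1 array per mouse, which gave 3 arrays against 3. The study's title speaks of isolating and characterising cancer stem cells, so the comparison asks which transcripts set the cells called tumorigenic apart from the remaining cells of the same tumours. Array medians were between 4.36 and 4.40 on the log2 scale. Control probe sets for 18S rRNA (3' end) read 7.15 ± 0.75 in the arrays labelled tumorigenic and 8.72 ± 0.23 in those labelled nontumorigenic (SD, n = 3 each). For Gapdh, the 3' control probe set exceeded the 5' one by 3.81, 6.60 and 2.62 log2 units in labelled tumorigenic mice 1 to 3, and by 3.78, 2.41 and 3.10 in the other population.

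The genes behind the sort gate were examined first, as a check of the labels. Ptprc, which encodes the leukocyte antigen CD45 that the gate excluded, read 10.21, 7.76 and 3.82 in the arrays labelled tumorigenic of mice 1, 2 and 3, and 2.33, 3.59 and 2.51 in those labelled nontumorigenic. Its means were 7.26 ± 3.23 and 2.81 ± 0.68 (SD, n = 3 each), a log2 difference of 4.45 (SE 1.54; limma adjusted p = 0.532), whose size is rough since the lower mean is dim. Cd24a, which encodes the CD24 surface protein used for positive selection, read 12.34 ± 0.50 and 12.90 ± 0.08 (SD, n = 3), a log2 difference of -0.55 (SE 0.27; limma adjusted p = 0.635), and each of its 3 probe sets had a negative difference. The Cd24a values of mice 1 to 3 were -1.02, -0.50 and -0.15, in the order of Ptprc, and without the labelled tumorigenic array of mouse 1 the difference was -0.31. Thy1, the other marker of positive selection, read 10.22 ± 0.79 and 9.99 ± 0.30 (SD, n = 3). Its log2 difference was 0.24, with a 95% interval from -0.78 to 1.25 (limma adjusted p = 0.898), and the values of mice 1 to 3 were 0.58, 0.84 and -0.72. Without the labelled tumorigenic array of mouse 1 the Thy1 difference was -0.069. As a list, these 3 markers did not pass (camera adjusted p = 0.836, and 0 members adjusted over the list alone). Ptprc thus went against the CD45-negative gate and Cd24a did not separate the populations in the direction of the gate, so the arrays are called labelled tumorigenic and labelled nontumorigenic throughout, and every direction given below is one between labels.

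**Figure D1:**
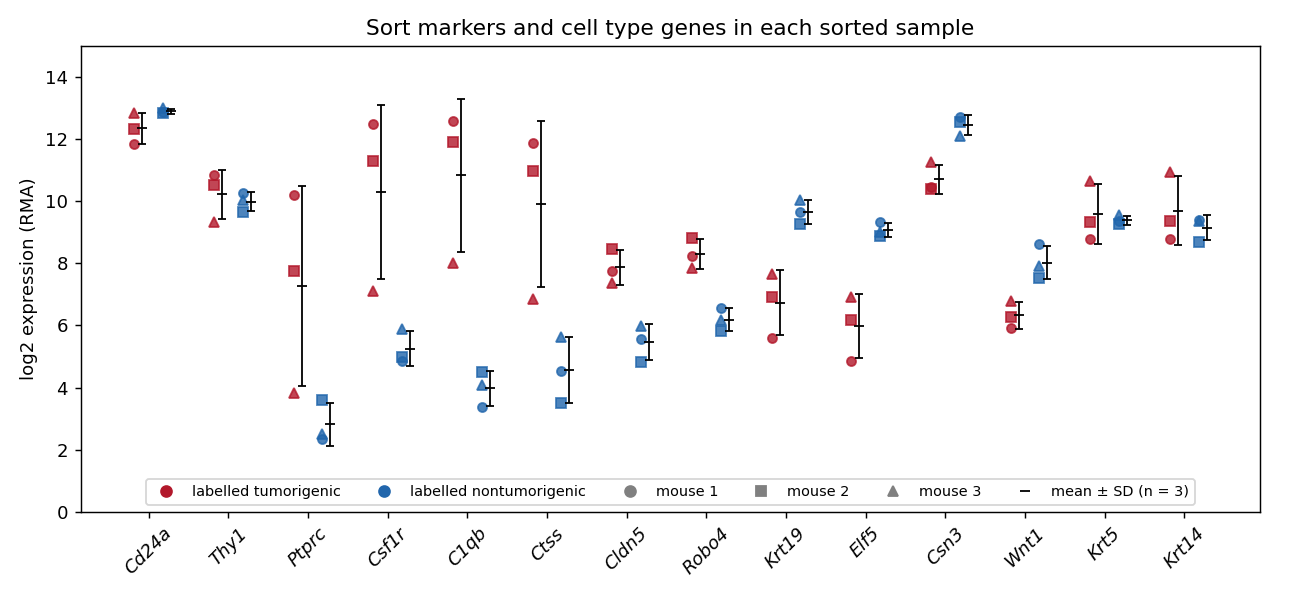
RMA log2 expression (vertical axis) of 14 sort marker and cell type genes on each of the 6 arrays, by labelled population, with the mean and SD of 3 arrays. Ptprc reads 10.21, 7.76 and 3.82 in the labelled tumorigenic arrays of mice 1, 2 and 3, while the labelled nontumorigenic arrays lie between 2.33 and 3.59.

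Across the transcriptome, no single gene separated the labels past the adjusted threshold. Ramp2, a partner of the calcitonin receptor-like receptor in adrenomedullin signalling, had the smallest p: it read 7.61 ± 0.17 in the arrays labelled tumorigenic and 5.20 ± 0.07 in those labelled nontumorigenic (SD, n = 3), a 5.34-fold difference with an SE of 0.16 log2 units (limma adjusted p = 0.0658). Hhipl2, related to the hedgehog-interacting protein, read 5.45 ± 0.20 and 8.27 ± 0.47 (SD, n = 3), a log2 difference of -2.82 (SE 0.28; limma adjusted p = 0.177). Of 15027 genes, 0 had a limma adjusted p below 0.05, with the mouse as a block 0 as well, and of 33777 probe sets 0. With the mouse as a block, the smallest limma adjusted p of any gene, Ramp2 included, was 0.363. An unadjusted p below 0.05 was found in 1277 genes, 786 with higher and 491 with lower values under the tumorigenic label, where 751 would be expected with no difference, and in 1435 genes with the mouse as a block. The ranges of the populations did not overlap in 1877 genes, 12.5%, against the 10% that chance gives for 3 arrays against 3. Without the labelled tumorigenic array of mouse 3, 18 genes passed, 16 of them higher and 2 lower, among them Ramp2 (adjusted p = 0.0424) and leukocyte genes such as C1qb, Csf1r, Tyrobp and Cd74, and 2308 genes had an unadjusted p below 0.05.

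By the rule for genes below the threshold, 12 genes in each direction are given as values only. On the higher side, log2 differences were 2.48 for Adgrl4, an adhesion receptor of endothelial cells, 1.49 for Cd93, a lectin-like receptor of endothelial and myeloid cells, 2.08 for the homeobox factor Hhex, 2.03 for the water channel Aqp1, and 1.30 for the transcriptional repressor Bcl6b. Further values were 3.26 for the membrane glycoprotein Gpm6a, 3.52 for the protocadherin Pcdh17, 1.62 for the large cadherin Dchs1, 3.11 for the collagenase Mmp13, 1.93 for the phosphatase subunit Ppp1r16b and 1.34 for the galectin Lgals9. The labelled nontumorigenic means of Gpm6a, Pcdh17 and Mmp13 were 2.34, 2.86 and 2.75, below the dim cut of 2.98, so the sizes of these differences are rough. Other probe sets gave 1.83 and 0.43 for Cd93 and 1.31 for Pcdh17. The limma adjusted p of these 11 genes lay between 0.177 and 0.221. On the lower side, log2 differences were -2.19 for Ehf, an ETS transcription factor of epithelial cells, -2.08 for the tight junction protein Cldn1, -2.03 for the calcium-activated potassium channel Kcnn4, -1.51 for the potassium channel Kcnk5, and -2.20 for Syne4, a nesprin of the nuclear envelope. The others were -3.40 for Apol7a, -2.21 for Psrc1, -2.06 for 2210407C18Rik, -1.58 for the polycomb group protein Pcgf6, -1.41 for Bspry and -1.33 for Cracdl. These values rest on the probe set chosen for each gene: other probe sets gave -0.19 and -0.29 for Pcgf6, -0.085 for Bspry, -0.46 for Syne4 and -1.20 for Cldn1, and the mean of a gene's probe sets gave -0.69 for Pcgf6, -0.75 for Bspry and -1.33 for Syne4. Their limma adjusted p lay between 0.177 and 0.22.

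**Figure D2:**
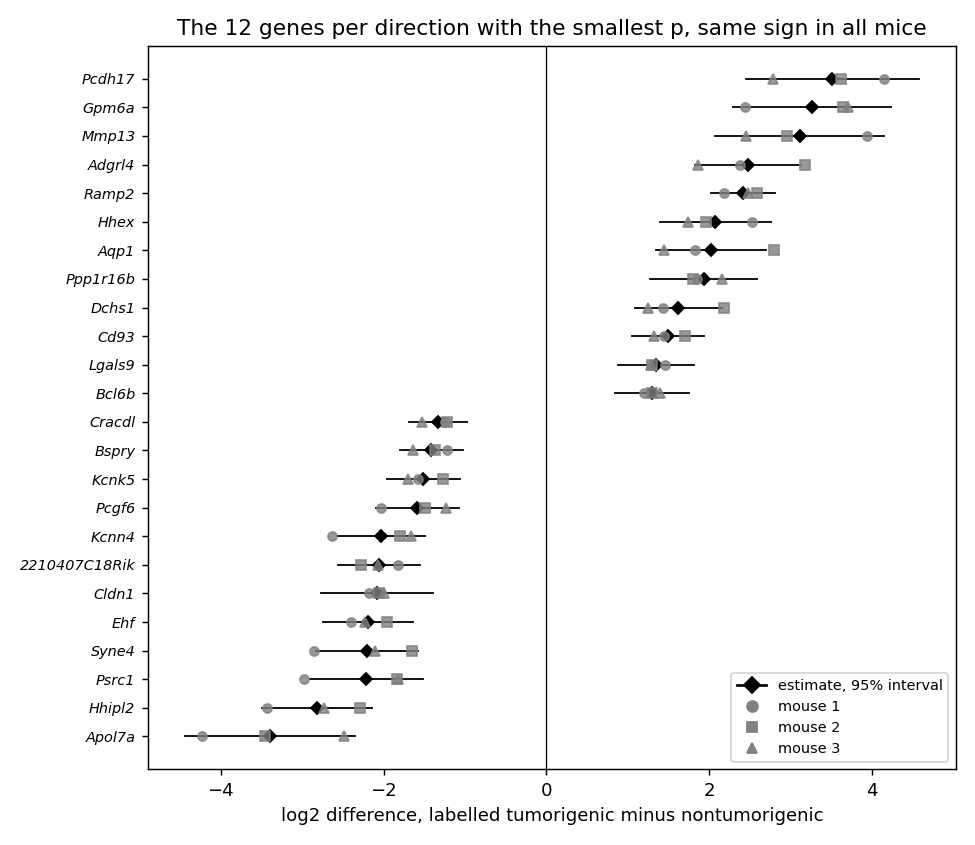
Log2 difference, labelled tumorigenic minus labelled nontumorigenic (horizontal axis), of the 12 genes per direction with the smallest p and the same sign in all 3 mice, with each mouse as a grey point and limma's estimate with its 95% interval in black. Ramp2, at 2.42, and Hhipl2, at -2.82, have the smallest p on their sides, and no gene passed the adjusted threshold.

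Of the 32 lists tested, 9 passed with camera at the preset correlation, 5 of them higher and 4 lower under the tumorigenic label. None of the 9 passed with an estimated correlation, and 0 lists passed by fry or by its mixed form. The 18S control probe sets and the leukocyte antigen Ptprc divided the arrays along the same labels as the lists described next. An alternative added after the data were seen set the labelled tumorigenic array of mouse 3, the one with the lowest Ptprc, alone against the other population. With 1 array on a side it holds no spread between mice there, so no call is drawn from it. On that array 13 of 19 macrophage and myeloid, 12 of 14 endothelial and 15 of 20 basal members lay above every labelled nontumorigenic array. Of luminal members 2 of 16 did, and of milk members 0 of 12. The T and NK cell, fibroblast and interferon lists pointed lower in that comparison, where the main fit pointed higher. With a leukocyte score as a covariate, also added later, endothelial and milk genes kept their calls (2.08e-04 and 2.31e-05) while luminal, adipocyte, MHC class II, polycomb, cell cycle and interferon response genes lost theirs (0.323, 0.0721, 0.806, 0.275, 0.670 and 0.214). The score is the mean of the macrophage and myeloid list, so the loss of that list's own call was fixed by the choice of covariate. It read 9.76, 8.15 and 5.28 in labelled tumorigenic mice 1 to 3, and 4.25, 4.11 and 4.21 in the other population. The score does not overlap between the labels, so calls kept, lost or gained under it cannot decide whether leukocyte content explains a list. With the score, basal, ribosomal and Wnt target and feedback genes passed as higher (4.84e-11, 2.31e-04 and 0.0354), and pericyte, fibroblast and T and NK cell genes passed as lower (2.78e-05, 4.33e-10 and 4.76e-06).

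Macrophage and myeloid transcripts showed the highest list median. Of 19 measured members, 17 had positive differences, and the median log2 difference was 3.86, or 6.38, 4.12 and 0.81 in mice 1, 2 and 3. C1qb, a chain of the complement component C1q, read 10.83 ± 2.47 in the arrays labelled tumorigenic and 3.97 ± 0.57 in those labelled nontumorigenic (SD, n = 3), a log2 difference of 6.85, or 8.26 without the labelled tumorigenic array of mouse 3. The low values are dim, so the size of this difference is a rough one. The mannose receptor Mrc1 read 8.79 ± 1.82 and 4.12 ± 0.64, the lysosomal protease Ctss 9.90 ± 2.67 and 4.55 ± 1.06, and the colony-stimulating factor receptor Csf1r 10.29 ± 2.81 and 5.24 ± 0.56 (SD, n = 3). The list was higher by camera (adjusted p = 3.49e-11), a call lost at an adjusted p = 0.525 with an estimated correlation. Over all genes 0 members passed, and adjusted over the list alone 13 passed. Ptprc read 10.21 and 7.76 in the 2 arrays in which these genes were highest, against a gate that excluded CD45.

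Antigen presentation genes of MHC class II moved with the myeloid genes. All 6 measured members had positive differences, with a median of 1.13, or 2.30, 1.31 and 0.19 in mice 1 to 3. The class II chain H2-Ab1 read 9.36 ± 2.54 and 4.85 ± 0.20, and the invariant chain Cd74 read 10.77 ± 2.37 and 6.63 ± 0.40 (SD, n = 3). H2-Aa had a log2 difference of 0.52 on its chosen probe set and of 3.92 and 3.76 on its others. Ciita, the class II transactivator, had 0.54, with probe sets of both signs. The list was higher by camera (adjusted p = 0.00130), with an adjusted p = 0.525 with an estimated correlation, and 2 members passed adjusted over the list alone against 0 over all genes.

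T and NK cell genes had a median of 1.12, which came from mouse 1: the medians of mice 1 to 3 were 3.13, 0.0086 and -0.033. Ccl5, a chemokine of activated T cells, had a log2 difference of 2.60 (SE 1.62), the interleukin-7 receptor Il7r 2.09 (SE 1.14), the protease Gzmb 1.20 and Cd4 0.38, with probe sets of both signs for Cd4 and labelled nontumorigenic means below the dim cut for Il7r and Gzmb. The list did not pass (camera adjusted p = 0.0662, 0 of 11 members adjusted over the list alone). With an estimated correlation its adjusted p was 0.861. By camera with the mouse as a block it passed (adjusted p = 0.0483) but by fry with the block it did not (0.783), and by camera it passed without the labelled tumorigenic array of mouse 2 (0.0135) or of mouse 3 (0.00143). B cell genes lay near the floor, with a median difference of 0.083 over 6 members: Cd79b 0.13, Pax5 0.13, Cd79a 0.091 and Blk 0.075 (camera adjusted p = 0.760, 0 adjusted over the list alone). Among neutrophil genes, S100a9 had a difference of 1.56, Mmp9 0.75, Camp -0.12 and Ngp -0.066. Their median was -0.066 while their mean was 0.38 and the test pointed up (camera adjusted p = 0.668, 0 of 5 adjusted over the list alone). Of the erythroid list 1 gene was measured, Slc4a1 with a difference of 0.11, and the list was not tested (0 adjusted over the list alone).

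Endothelial genes were higher under the tumorigenic label in all 3 mice, with a median log2 difference of 1.38, or 0.87, 1.65 and 1.12 in mice 1, 2 and 3. All 14 measured members had positive differences. Robo4, a guidance receptor of vessels, read 8.29 ± 0.48 in the arrays labelled tumorigenic and 6.19 ± 0.36 in those labelled nontumorigenic, and the endothelial tight junction protein Cldn5 read 7.87 ± 0.56 and 5.46 ± 0.59 (SD, n = 3). Kdr, a receptor for vascular endothelial growth factor, differed by 3.27-fold and the receptor kinase Tie1 by 4.32-fold. The list was higher by camera (adjusted p = 1.15e-11), a call lost at an adjusted p = 0.457 with an estimated correlation, and 12 members passed adjusted over the list alone, against 0 over all genes. Adipocyte genes were higher as well, with a median of 0.76 over 6 members, 5 of them positive, or 0.64, 1.46 and 0.48 in mice 1 to 3. Car3, a carbonic anhydrase abundant in adipocytes, read 8.996 ± 1.77 and 3.38 ± 0.59 (SD, n = 3), with the labelled nontumorigenic values near the dim cut, and its other probe sets gave log2 differences of only 0.23 and 0.49. The adipokine Adipoq had a log2 difference of 3.04, the regulator Pparg 0.76 and the lipid droplet protein Cidec 0.62. Mouse 2 carried much of these: Adipoq differed by 1.58, 5.85 and 1.68 in mice 1 to 3, Pparg by 0.57, 1.16 and 0.56, and Cidec by -0.074, 1.75 and 0.18, and Adipoq was below the dim cut in the labelled nontumorigenic mean. The labelled tumorigenic array of mouse 2 is also the one that stood apart in its Gapdh, actin and 18S controls, though the list passed without it (adjusted p = 0.0233). The adipocyte list passed by camera (adjusted p = 0.00745), with an adjusted p = 0.614 with an estimated correlation, and 1 member, Car3, passed adjusted over the list alone, against 0 over all genes.

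Luminal epithelial genes were lower under the tumorigenic label. Of 16 measured members 15 had negative differences, with a median of -1.51, or -2.70, -0.60 and -1.22 in mice 1, 2 and 3. Elf5, a transcription factor of luminal progenitor and alveolar cells, read 5.98 ± 1.04 in the arrays labelled tumorigenic and 9.08 ± 0.22 in those labelled nontumorigenic, and the keratin Krt19 read 6.73 ± 1.04 and 9.65 ± 0.40 (SD, n = 3). Ehf was at a 4.58-fold lower level, and the claudin Cldn3 had a log2 difference of -1.67. The list was lower by camera (adjusted p = 5.73e-09), a call lost at an adjusted p = 0.525 with an estimated correlation. Adjusted over the list alone, 3 members passed, namely Ehf, Elf5 and Krt19, against 0 over all genes. The differences did not follow Ptprc across mice: the array with the highest Ptprc, of mouse 1, had the lowest median, but mouse 3, with the lowest Ptprc, had a lower one than mouse 2.

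Milk and secretory genes were lower too: all 12 measured members had negative differences, with a median of -1.91, or -2.41, -2.14 and -0.74 in mice 1 to 3. The casein Csn3 read 10.70 ± 0.47 and 12.45 ± 0.31, the iron-binding milk protein Ltf 8.21 ± 0.55 and 11.00 ± 0.87, and Btn1a1, a protein of the milk fat globule, 8.73 ± 0.87 and 10.89 ± 0.40 (SD, n = 3). For the casein Csn1s1 the log2 difference was -3.48, or 11.1-fold. The list passed by camera (adjusted p = 2.32e-08), with an adjusted p = 0.457 with an estimated correlation, and 7 members passed adjusted over the list alone, against 0 over all genes. Genes of hormone-sensing luminal cells did not pass as a list (median -0.16 over 7 members, camera adjusted p = 0.0936, 0 adjusted over the list alone). Their log2 differences were -0.63 for the secretory regulator Xbp1, -0.81 for Gata3, -0.84 for the pioneer factor Foxa1 and 0.19 for the oestrogen receptor Esr1.

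Basal and myoepithelial genes separated mouse 3 from the others, with medians of -0.23, -0.055 and 1.20 in mice 1, 2 and 3 and a median of 0.19 over the 3 mice. The smooth muscle protein Tagln had a log2 difference of 0.64 (SE 0.18), the keratin Krt17 0.65, calponin Cnn1 0.87 and the growth factor receptor Egfr 0.45, with Egfr probe sets of both signs. The list did not pass (camera adjusted p = 0.161, 0 of 20 adjusted over the list alone). At the preset correlation it passed as higher without the labelled tumorigenic array of mouse 1 (camera adjusted p = 0.00525) or mouse 2 (0.0365). With all 6 arrays its adjusted p was 0.906 by camera with an estimated correlation and 0.754 by fry. Fibroblast genes had medians of 0.88, 0.50 and -0.93 in mice 1 to 3. Serpinf1 had a difference of 0.79, Prrx1 0.22 with probe sets of both signs, Twist2 0.68 and the proteoglycan Dcn 0.35. The fibroblast list did not pass (camera adjusted p = 0.644, 0 of 14 adjusted over the list alone) and passed as higher without the labelled tumorigenic array of mouse 3 (adjusted p = 6.43e-05). Pericyte genes had a median of 0.049, with differences of 0.61 for Des, -0.30 for Notch3, 0.56 for Kcnj8 and -0.21 for Rgs5, and probe sets of both signs for Des and Rgs5. Their median was positive while the test pointed down (camera adjusted p = 0.977, 0 of 8 adjusted over the list alone).

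Among Wnt ligands and receptors, Wnt1, the gene that the transgene overexpresses in these tumours, read 6.32 ± 0.43 in the arrays labelled tumorigenic and 8.03 ± 0.54 in those labelled nontumorigenic (SD, n = 3), with log2 differences of -2.69, -1.28 and -1.15 in mice 1 to 3. It was the 1 member of this list to pass adjusted over the list alone (adjusted p = 0.0496), while its limma adjusted p over all genes was 0.314. Fzd2 had a difference of 0.48, Wnt5b -0.82 and Wnt5a -0.52, with Wnt5a probe sets of both signs. The list as a whole did not pass (median 0.0068 and mean -0.093 over 19 members, camera adjusted p = 0.748). Wnt target and feedback genes did not pass either (median 0.36 over 18 members, camera adjusted p = 0.244, 0 adjusted over the list alone), though they did as higher with the leukocyte score as a covariate (0.0354). In that list the secreted antagonist Sfrp1 had a difference of 1.52, cyclin D1 (Ccnd1) -0.66, Apcdd1 0.67 with probe sets of both signs, and the transcription factor Lef1 0.93.

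Other signalling lists stayed below the threshold. In the Notch pathway, Notch4, a receptor of vascular endothelium, read 7.73 ± 0.46 and 5.67 ± 0.55 (SD, n = 3) and passed adjusted over the list alone (adjusted p = 0.0157), the 1 member of 14 to do so. Nrarp had a difference of -0.63, Lfng 1.05 and the ligand Dll4 0.98, with probe sets of both signs for Nrarp and Lfng (list median 0.022, camera adjusted p = 0.842). Hedgehog genes had a median of 0.15 over 9 members, with differences of -0.42 for Shh, 0.76 for Dhh, 0.42 for Smo and 0.30 for Ptch1, and probe sets of both signs for Dhh and Ptch1 (camera adjusted p = 0.748, 0 adjusted over the list alone). For TGF-beta and BMP genes the median was 0.15 over 14 members, with 1.28 for Tgfb1, -0.55 for Tgfb2, 0.81 for Bmp2 and -0.64 for Ltbp1 (camera adjusted p = 0.658, 0 adjusted over the list alone).

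Genes of the epithelial-mesenchymal transition had a median of 0.21, and 11 of 12 measured members were positive. The fibronectin receptor subunit Itga5 read 9.16 ± 0.51 and 7.75 ± 0.23 (SD, n = 3) and was the 1 member to pass adjusted over the list alone (adjusted p = 0.0346). Mmp2 had a difference of 0.54, Fn1 0.64 and Twist1 0.24, and Itga5 and Fn1 had probe sets of both signs. The list did not pass (camera adjusted p = 0.0580) but passed as higher without the labelled tumorigenic array of mouse 2 (adjusted p = 0.0112) or mouse 3 (0.0338). Genes associated with stem cells did not pass (median 0.12 and mean -0.012 over 15 members, camera adjusted p = 0.864, 0 adjusted over the list alone). Of these, the surface receptor Procr had a difference of 1.09, Sox9 -1.02, the transporter Abcg2 0.73 and the integrin Itgb3 0.73.

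Proliferation genes were lower under the tumorigenic label, with a median of -0.51, or -0.50, -0.96 and -0.035 in mice 1 to 3, and 20 of 23 measured members negative. The mitotic kinase Aurka read 4.21 ± 0.36 and 5.20 ± 0.28, and the proliferation antigen Mki67 read 8.39 ± 1.03 and 9.55 ± 0.58 (SD, n = 3). Cdc20 had a log2 difference of -0.67 and Birc5 -1.11. The cell cycle list was lower by camera (adjusted p = 2.71e-04), with an adjusted p = 0.716 with an estimated correlation and 0 members adjusted over the list alone or over all genes, and it did not pass without the labelled tumorigenic array of mouse 2 (adjusted p = 0.165). That array had the lowest mean of the cell cycle list, 6.13, and also stood apart in its controls, with the highest 3' excess for Gapdh (6.60) and actin (3.72) and the lowest 18S value (6.32), so RNA quality may bear on this list. Polycomb and chromatin repressor genes were lower as well, with a median of -0.10, or -0.25, -0.41 and -0.18 in mice 1 to 3, and 11 of 13 negative. Ezh1 had a difference of -0.69 with probe sets of both signs, the methyltransferase Dnmt1 -0.51, the polycomb methyltransferase Ezh2 -0.60 and Dnmt3b -0.57. That list passed by camera (adjusted p = 0.0389), with an adjusted p = 0.525 with an estimated correlation and 0 members adjusted over the list alone or over all genes. It did not pass without the labelled tumorigenic array of mouse 2 (adjusted p = 0.0746) or mouse 3 (0.0622) or the labelled nontumorigenic array of mouse 2 (0.110).

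Inhibitors of cyclin-dependent kinases did not pass (median 0.14 and mean -0.015 over 7 members, with the test pointing down, camera adjusted p = 0.836, 0 adjusted over the list alone). Differences were -0.25 for Cdkn1b, 0.29 for Cdkn2c, -0.47 for Cdkn1a and 0.17 for Cdkn2d. DNA repair genes had a median of -0.19 over 17 members, with -0.89 for the checkpoint kinase Atr, 0.40 for Nbn, -0.77 for Chek2 and -0.79 for Fancd2, and Atr probe sets of both signs. This list did not pass (camera adjusted p = 0.151, 0 adjusted over the list alone) and passed as lower without the labelled nontumorigenic array of mouse 2 (adjusted p = 0.0374).

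Interferon response genes were higher under the tumorigenic label, with a median of 0.70, or 0.61, 0.93 and -0.085 in mice 1 to 3, and 11 of 12 members positive. Ifit2 read 6.70 ± 0.78 and 5.17 ± 0.48 (SD, n = 3), Stat2 had a difference of 0.82, Bst2 0.56 and Irf1 0.82. The list passed by camera (adjusted p = 0.00353), with an adjusted p = 0.698 with an estimated correlation and 0 members adjusted over the list alone or over all genes, and it did not pass without the labelled tumorigenic array of mouse 1 (adjusted p = 0.0555) or mouse 2 (0.0746), the 2 arrays with the highest Ptprc. Among antioxidant genes, the haem oxygenase Hmox1 read 7.45 ± 0.73 and 5.69 ± 0.24 (SD, n = 3) and was the 1 member of 13 to pass adjusted over the list alone (adjusted p = 0.0479). The regulator Nfe2l2 had a difference of 0.49, Gsr -0.44 and Gpx1 0.32 (list median 0.070, camera adjusted p = 0.644).

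Basement membrane and laminin genes had a median of 0.18 over 13 members, with 0.52 for Lamb1, 0.78 for Lama4, 0.60 for Nid2 and 0.81 for Hspg2. They did not pass (camera adjusted p = 0.0737, 0 adjusted over the list alone) and passed as higher without the labelled tumorigenic array of mouse 2 (adjusted p = 0.0426). Immediate early and dissociation stress genes differed little, with a median of 0.041 over 15 members and values of 0.33 for Junb, 0.18 for Zfp36, 0.24 for Ier3 and 0.16 for Atf3 (camera adjusted p = 0.613, 0 adjusted over the list alone). Hypoxia and glycolysis genes had a median of 0.18 over 15 members, with -1.22 for Car9, 0.66 for Hk2, 0.50 for Vegfa and 0.37 for Pfkp, which had probe sets of both signs (camera adjusted p = 0.644, 0 adjusted over the list alone, and 0.0459 as higher without the labelled tumorigenic array of mouse 1). Ribosomal protein genes had a median of 0.031 over 15 members, with 0.27 for Rps14, -0.14 for Rpl27, 0.16 for Rps18 with probe sets of both signs and 0.068 for Rpl19 (camera adjusted p = 0.864, 0 adjusted over the list alone, and 0.0357 as higher without the labelled tumorigenic array of mouse 1). Oxidative phosphorylation genes had a median of 0.024 and a mean of -0.014 over 17 members, with -0.47 for Uqcrfs1, -0.75 for Ndufa4, 0.34 for Sdhb and 0.23 for Ndufb5 (camera adjusted p = 0.977, 0 adjusted over the list alone).

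**Figure D3:**
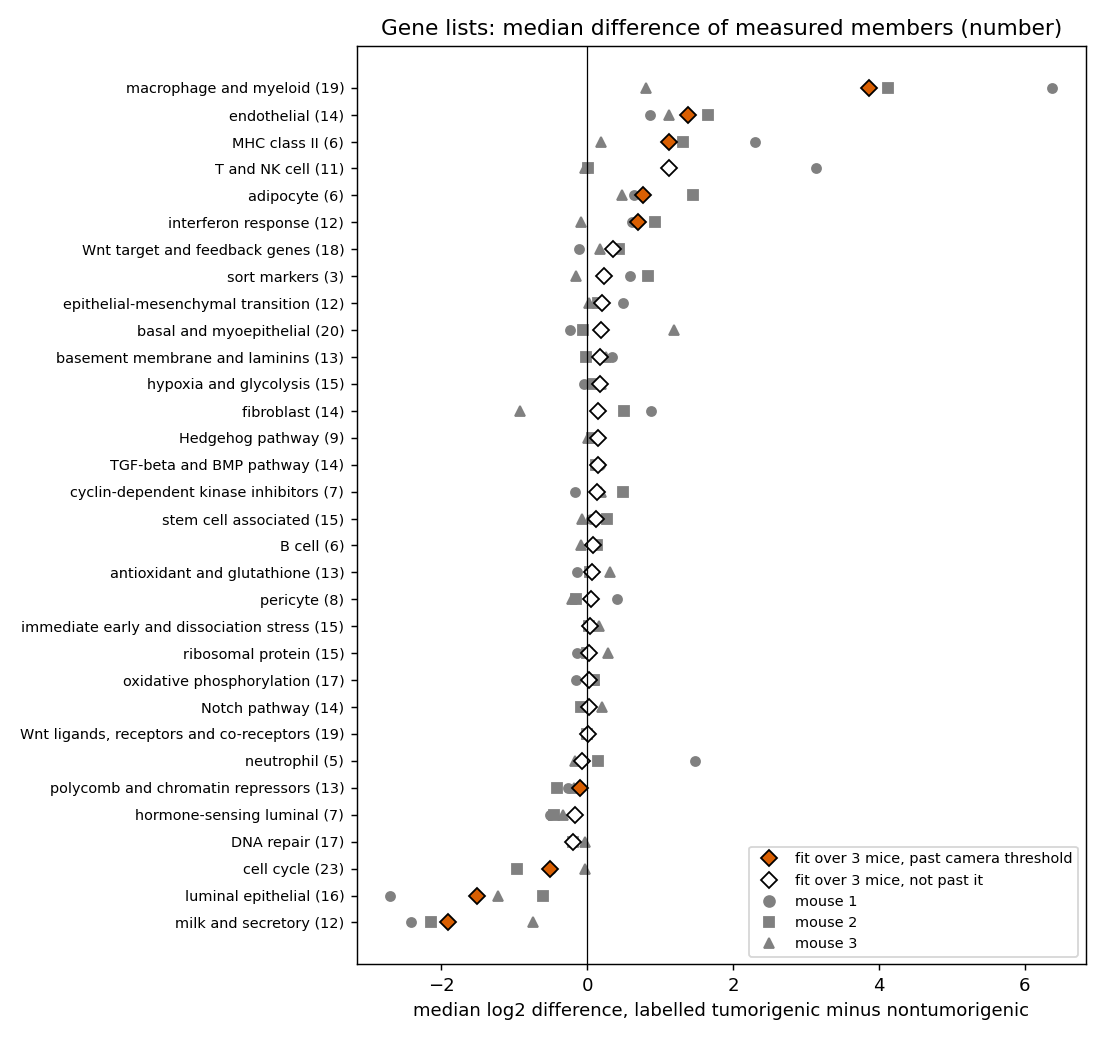
Median log2 difference of each gene list, labelled tumorigenic minus labelled nontumorigenic (horizontal axis), as a diamond that is filled where the list passed by camera at the preset correlation, with the median of each mouse as a grey point. Macrophage and myeloid genes have the highest median, 3.86, with mouse 3 at 0.81, and milk genes the lowest, -1.91.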

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

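The alternatives with mouse 3 alone and with the leukocyte score were chosen after the data were seen, and the others were planned. By limma, genes past the adjusted threshold numbered 0, but 1, Ramp2, without a dim filter (adjusted p = 0.0491) or with the mean of a gene's probe sets (0.0415), against 0.0424 to 0.878 when an array or mouse was left out. The count of probe sets was 0, but 1 with a trended and robust prior. Leaving out each array or mouse gave 0 to 18 genes, 726 to 2308 with an unadjusted p below 0.05 (431 to 1359 higher, 264 to 949 lower), 0 to 8 probe sets, 1664 to 4208 with an unadjusted p below 0.05 (883 to 2333 higher, 779 to 1875 lower). Leaving out each array gave 9 to 11 lists, which were not rerun without a mouse. The highest gene counts came without the labelled tumorigenic array of mouse 3. With the mouse as a block, 1435 genes had an unadjusted p below 0.05 and 10 lists passed, T and NK cell genes in addition, and it changed no other call. Lists past the threshold numbered 0 with an estimated correlation and 0 by fry. For camera only the setting of the correlation between genes differed, so the loss of calls there follows from that setting. At the preset correlation, the arrays split otherwise than by label gave up to 12 lists, where the labels gave 9. Calls at the preset correlation therefore do not by themselves set the labels apart. Why fry gave 0 was not tested further. With the mean of a gene's probe sets, the polycomb list lost its call (adjusted p = 0.0747).

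With mouse 3 alone as labelled tumorigenic, whose spread is taken from the 3 other arrays, 0 genes and 11 lists passed, 679 probe sets were lower at an unadjusted p below 0.05, and Thy1 turned to -0.66. Camera p-values of lists that turned were 0.00762 (T and NK cell, lower), 1.31e-09 (fibroblast, lower) and 0.296 (interferon response, lower). With the leukocyte score, which takes up much of the difference between populations, 327 genes and 677 probe sets were lower at an unadjusted p below 0.05. Over both directions, 751 such genes would be expected with no difference. Under the score Thy1 turned to -0.999, Cd24a to 0.21 and Ptprc to -0.54. List p-values that turned were 0.0270 (macrophage and myeloid, whose mean is the score), 0.663 (MHC class II), 4.46e-07 (T and NK cell), 2.71e-11 (fibroblast) and 0.114 (interferon response). Thy1 ranged from -0.069 without the labelled tumorigenic array of mouse 1 (-0.066 without mouse 2) to 0.712 without mouse 3. The cause of these turns was not tested beyond the make-up of each alternative. Dim signals limit the B cell, neutrophil and erythroid lists.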

Other observations

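All tests in this part were chosen after the results they bear on were seen. Genes of lymphatic endothelium, a vessel type outside the planned lists, had 7 of 7 measured members positive under the tumorigenic label, with a median log2 difference of 1.19, or 0.74, 1.86 and 1.02 in mice 1, 2 and 3. Flt4, the receptor for lymphatic growth factors, read 8.60 ± 0.28 in the arrays labelled tumorigenic and 6.01 ± 0.72 in those labelled nontumorigenic, and Prox1, the transcription factor that specifies lymphatic identity, 7.31 ± 0.37 and 6.12 ± 0.52 (SD, n = 3). The list was higher by camera (adjusted p = 1.84e-05 over the 5 lists added here), with an adjusted p = 0.0705 with an estimated correlation. The Gimap family, GTPases of lymphocytes and endothelial cells, had 8 of 8 members positive with a median of 1.47, or 1.78, 0.72 and 1.17 in mice 1 to 3 (adjusted p = 6.84e-06, and adjusted p = 0.133 with an estimated correlation), with differences of 3.00 for Gimap4 and 1.93 for Gimap5.

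Fatty acid synthesis genes were lower under the tumorigenic label, with 12 of 15 members negative and a median of -0.48, or -1.07, -0.25 and -0.22 in mice 1 to 3. Thrsp, a regulator of lipogenesis in mammary gland and liver, read 7.27 ± 0.38 and 9.63 ± 0.53, and the acetyl-CoA synthetase Acss2 7.83 ± 0.13 and 8.82 ± 0.15 (SD, n = 3). That list passed by camera (adjusted p = 1.64e-05), with an adjusted p = 0.133 with an estimated correlation. Chemokines of the CC class had a median of 0.20, or 1.29, 0.49 and -0.021 in mice 1 to 3, with 11 of 16 members positive (adjusted p = 0.0198, and adjusted p = 0.320 with an estimated correlation). Ccl8 differed by 6.72, 5.05 and 1.45 and Ccl6 by 6.29, 5.15 and 0.83 in mice 1 to 3, so both were highest where the leukocyte genes were. Matrix metalloproteinases and their inhibitors had a median of 0.75, or 1.03, 1.41 and -0.27 in mice 1 to 3, with 14 of 17 positive (adjusted p = 4.04e-04, and adjusted p = 0.280 with an estimated correlation). They were lowest in mouse 3, as were the fibroblast medians (0.88, 0.50 and -0.93) and the macrophage and myeloid medians (6.38, 4.12 and 0.81). A link between these was not tested. Of the 5 added lists, 0 members passed over all genes by limma.

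Leukocyte genes, which a CD45-negative gate would remove, were higher in the arrays labelled tumorigenic, most of all in mice 1 and 2. In both of these arrays 89.5% of the macrophage and myeloid members, 17 of 19, lay above every labelled nontumorigenic array, and in mouse 3, whose Ptprc was low, 13 did, with C1qb at 12.58, 11.89 and 8.01 in mice 1 to 3 and Cd74 at 12.72, 11.47 and 8.13, and only 2 members had a mean above log2 5 in the labelled nontumorigenic arrays. Leukocytes carried into the gate stay open as an explanation, since these counts restate the pattern and do not test it, and an exchange of the labels of the 2 populations predicts the same values if the other gate let CD45-positive cells in, which its label does not settle. Cd24a was lower in 3 of 3 mice (-1.02, -0.50 and -0.15), which goes with an exchange but also follows the order of the leukocyte genes, and the Thy1 difference of 0.24 has an interval on both sides of 0, so the exchange stays open. Whether the tumorigenic cells themselves carry these transcripts also stays open. The lowest of the 3 mouse medians was 0.81, neither below 0 nor above 1 log2 unit, limits that were set after the data were seen. A median above 1 would also follow from carried leukocytes or exchanged labels, so this value does not decide.

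Luminal and milk genes were lower in the arrays labelled tumorigenic. Dilution of all other cells by leukocytes, with no further difference, would lower basal, luminal and milk genes alike. Yet the basal median exceeded the luminal one by 1.81 on average (SD 1.10 over 3 mice, values 2.47, 0.55 and 2.42) and the milk one by 2.06 (SD 0.12). The luminal median of mouse 3, with fewer leukocyte transcripts, was -1.22, lower than that of mouse 2 at -0.60. These values argue against dilution as the whole cause. They do not show what else differed, since basal genes were not measured in epithelial cells alone. The milk medians of mice 1 to 3, -2.41, -2.14 and -0.74, were lowest where the leukocyte genes were highest. So were the basal medians, at -0.23, -0.055 and 1.20. Dilution on top of another difference therefore stays open. With the leukocyte score as a covariate the luminal list lost its call (camera adjusted p = 0.323). Its median moved from -1.51 (SD 0.96 over members) to -0.21 (SD 1.03), while basal genes moved from 0.19 to 1.31, so the score shifted both. Milk genes kept a median of -1.36 (camera adjusted p = 2.31e-05 at the preset correlation). For luminal and milk genes alike the fit with the score cannot decide, since the score does not overlap between the labels. Without the score, the milk call was lost with an estimated correlation (camera adjusted p = 0.457). A sort that took fewer luminal cells into the population labelled tumorigenic stays open: the luminal median lay below the basal one in 3 of 3 mice, which cannot be told apart from lower expression per cell in these bulk samples. A difference between tumorigenic and other cells of the design stays open as well, untested. An exchange of the labels, left open for the leukocyte genes, would reverse this direction and stays open here too.

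Endothelial genes were higher in the arrays labelled tumorigenic of all 3 mice, and 100% of the 14 members were higher in at least 2 mice. Endothelial cells inside a gate set on CD24 and Thy stay open as an explanation that these counts do not test, and 13 of the 14 members had a mean above log2 5 in the labelled nontumorigenic arrays too, with Robo4 at 6.19 and Cldn5 at 5.46. The endothelial medians of mice 1 to 3 were 0.87, 1.65 and 1.12, and did not follow the macrophage and myeloid medians of 6.38, 4.12 and 0.81. This order argues against leukocyte content of the same arrays as the whole cause. With the leukocyte score as a covariate the list kept its call at the preset correlation (camera adjusted p = 2.08e-04), with a median of 0.90 against 1.38 before. That fit cannot decide, since the score itself differs between the labels. Without the score, the call was lost with an estimated correlation (camera adjusted p = 0.457). Expression by the tumorigenic cells themselves and an exchange of the labels both stay open, untested.

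The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The counts of genes and of probe sets past the adjusted threshold were 0 in the real split and 0 at most in the others, so 10 of 10 splits were as large by definition and the comparison says nothing. For genes with an unadjusted p below 0.05 the real split gave 1277 and the highest other 1256, so 1 of 10 was as large, and for probe sets 2599 and 2500, again 1 of 10. For gene lists the real split gave 9 and the highest other 12, and 4 of 10 splits were as large. The 3 other splits that kept the labelled tumorigenic arrays of mice 1 and 2 together gave 920, 1076 and 1256 genes, and the remaining 6 gave 285 to 602, which points to a structure in which these 2 arrays stand apart. Among the splits that separate the arrays of every mouse, as the real one does, the others gave 920, 384 and 285 genes, and the 6 further splits keep both arrays of at least 1 mouse together. Across probe sets, which are not independent replicates, the labelled tumorigenic array of mouse 3 correlated with the labelled nontumorigenic arrays at 0.967 to 0.972, and with the labelled tumorigenic arrays of mice 1 and 2 at 0.954 and 0.965.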
